A study of Mus musculus with 11 samples.

How the data were processed

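RNA sequencing of mouse gingival epithelium, 11 libraries, was analysed from 1 deposited table. The labels describe male B6 mice, gingiva treated with Dispase so that the epithelium could be lifted off, polyA selection and a strand-preserving library kit. The 11 libraries fell into 3 groups by their titles, which were naive (n = 4), ligature in place (n = 3) and ligature removed (n = 4). The labels place the removal on day 3 and do not give the day on which tissue was collected. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries. Replicates differed by more than counting noise (the smallest chi-square per degree of freedom between libraries of a group was 20.4), and none was merged.

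The deposited table held 993339 rows, of which 993161 were empty and 178 named a gene. For each gene it gave 3 values per library. Raw counts were whole numbers deposited by the authors. The normalised read counts deposited by the authors, a signal never below 0, equalled the raw counts divided by 1 size factor per library (0.757 to 1.21, largest absolute deviation 0.0032 normalised counts). Batch-corrected values deposited by the authors were on the same linear scale, with 7 values below 0 in 3 genes. The submitters' processing notes name cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01, DESeq2 1.36.0 and the build GRCm39, without roles. The correction method, its batches and the strand setting of the counting are not given in the sources used here. Of the 178 gene identifiers, 177 were found in the reference list of mouse gene names. The reference genome at hand was of another build, so no coordinates are printed.

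The counts of the 178 genes summed to between 282274 and 503570 per library. These sums cover a small part of each library and are not its depth, which is unknown. Size factors computed on the 178 genes alone would assume that most of them did not change, so the deposited size factors were used for scaling. This departs from the design written before the data were examined, which scaled with TMM factors over all genes; that scaling is printed beside the main counts. All 178 genes had an unadjusted p of at most 0.0103 in DESeq2 with the deposited size factors and a batch term, in ligature or removal against naive. The table therefore appears to hold genes selected on these groups. Counts of changed genes are not counts over the transcriptome, adjusted p-values are corrected over the genes of the table alone, and directions within the table are not independent evidence.

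The batches were read from the deposited correction. Among all 957 ways to divide the libraries in 2 sets that were tried, 1 made the corrected values a linear function of the normalised counts within each set (median residual 4.2e-05% of the mean, against 1.71% for the next). Set A held naive replicates 1 and 2, ligature replicate 1 and removal replicates 2, 3 and 4. Set B held naive replicates 3 and 4, ligature replicates 2 and 3 and removal replicate 1. The labels give no batch, and the sets were derived without the group labels.

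Raw counts were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood F test, 1 fit of all 11 libraries with a mean per group, the default expression filter by group and Benjamini-Hochberg adjustment over the 176 genes tested. Genes were called at an adjusted p under 0.05, two-sided. The filter left out 2 genes, Smr2 and Usp9y. Values are given as normalised read counts, mean ± SD, with the log2 fold change ± SE of the fit. Named genes followed a rule fixed before the data were examined: in each comparison the 5 largest changes in each direction among called genes with a mean log2 CPM of 2 or more, without predicted models, pseudogenes and ribosomal protein genes, the 2 members with the smallest adjusted p from each pathway list, and 1 from each cell type list. CPM here refers to table totals, so that floor equals about 1.6 counts and removed little. The rule named 23, 21 and 18 genes, of which some are not reported. Other genes named in the text were chosen after their values were seen.

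Before the data were examined, 31 gene lists were fixed, 14 of pathways and 17 of cell types, with 462 genes. Of these genes 17 were in the table, 10 lists had a member and 3 lists had the 3 members needed for a set test. After the gene names of the table had been seen, 4 further lists were written (immediate early and rapid-response genes, heat shock chaperones, mitosis and chromosome maintenance, and NF-kappaB and Toll-like receptor signalling). Lists were tested with camera in limma 3.58.1 (prior count 2, preset correlation 0.01), with camera at an estimated correlation and with fry; p-values were adjusted over the lists of the same kind. Camera compares a list with the other genes of this selected table, not with the transcriptome.

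Alternatives covered TMM, median-of-ratios and upper-quartile factors over the table, a looser and a stricter count filter, a robust fit, fits of the compared groups alone, DESeq2 1.42.0, the replicate number as a block, a batch term, limma on the log2 of the batch-corrected values (pseudocount 1) and leaving out each library in turn. Exact Poisson-based 95% intervals for ratios of low counts cover counting error only. The count test was tested on simulated data for ligature against naive, with 60 of the 178 genes changed in each of 10 rounds. It recovered 55% of genes changed 1.5-fold, 88.5% of those changed 2-fold and 100% of those changed 4-fold, and called 1.21% of unchanged genes. The simulation held no set effects and no selection of genes, and it changed fewer genes than were called in the data. These rates therefore need not hold for this table. Computation used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.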

Results

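RNA was sequenced from the gingival epithelium of mice labelled as male, in 3 groups. Usp9y, a gene of the Y chromosome, had counts in removal replicate 1 alone (30 counts). It was left out by the count filter, and no other gene of that chromosome was in the table. These data therefore neither bear out nor contradict the label for the other libraries. Naive mice (n = 4 libraries) had no ligature. In the ligature group (n = 3) a silk thread stayed around the upper second molars, where it holds bacterial plaque against the gum and sets off periodontitis. In the removal group (n = 4) the thread was taken off on day 3. The comparisons ask how the epithelium differs with the ligature in place and what differs once it has been taken off. The table holds a selected set of genes, with 282274 to 503570 counts per library over those genes. Every gene in it had an unadjusted p of at most 0.0103 for ligature or removal against naive in DESeq2 with a batch term, and 162 of the 176 tested had one under 0.05 in edgeR without that term.

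With the ligature in place, transcripts of Areg and Hbegf and of the measured antimicrobial and rapid-response genes were lower than in naive epithelium. Those of the 5 measured genes of a list of mitosis and chromosome maintenance (the mitosis list) were higher. The mitosis and rapid-response lists were written after the gene names of this selected table had been seen. Measured members are those present in this table: 3 of 21 antimicrobial, 30 of 40 rapid-response and 5 of 11 mitosis list genes. The selection favours a call for each of them, and absent members may have been sequenced without being selected. Areg (ENSMUSG00000029378), a ligand of the epidermal growth factor receptor, fell from 130.8 ± 20.5 normalised counts (SD, n = 4) to 46.06 ± 2.84 (n = 3), a log2 fold change of -1.50 ± 0.30 (SE; edgeR quasi-likelihood test, adjusted p = 0.00192). Hbegf, a ligand of the same receptor, fell by 1.27 ± 0.21 on the log2 scale (adjusted p = 0.000601 in edgeR), and the beta-defensin Defb14 fell by 0.88 ± 0.18 (adjusted p = 0.00233 in edgeR). Mki67 (ENSMUSG00000031004), a marker of cycling cells, rose from 3426 ± 152 (n = 4) to 4938 ± 623 (n = 3), a log2 fold change of 0.53 ± 0.12 (edgeR adjusted p = 0.00371).

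Of 176 genes tested, 150 were called between ligature and naive, 50 higher and 100 lower. With TMM factors over the table the count was 114, 64 higher and 50 lower, so the share of higher calls was 33.3% with the deposited size factors and 56.1% with TMM. That change of scale moved the median log2 fold change of all tested genes from -0.38 to -0.02, and every log2 value here is relative to the deposited scale. All 150 calls had the same direction within each of both library sets read from the deposited batch correction, and all 150 were among the 157 called with a batch term. The genes of the table had all differed between groups in a test with such a term, so this agreement was largely fixed in advance. In 131 genes the libraries of the groups did not overlap, against 5.71% of genes by chance, though the genes of this table were selected for such differences.

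Among genes with the largest falls, Arc (ENSMUSG00000022602), an activity-induced immediate early gene, dropped from 224.8 ± 41.9 (n = 4) to 36.4 ± 5.57 (n = 3). Its log2 fold change was -2.62 ± 0.35 (edgeR adjusted p = 0.000224). Bpifa5, of a family of secreted bactericidal/permeability-increasing fold proteins, Fam71a, Stpg3 and Iqcn also fell, with log2 fold changes of -2.58, -5.14, -2.70 and -2.57. Fam71a had 20 to 168 counts in naive libraries and 1 to 4 in ligature libraries. Leaving out predicted gene models, the genes with the largest rises were Scgb2b12, Ccer2, Fam81a, Ppp1r3b and Msi1. Ppp1r3b, a subunit that directs protein phosphatase 1 to glycogen, rose from 226.9 ± 34.2 to 468.5 ± 122, a log2 fold change of 1.05 ± 0.21 (edgeR adjusted p = 0.00231). Msi1, an RNA-binding protein of progenitor cells, rose by 0.94 ± 0.20. The secretoglobin Scgb2b12 had 1 count in all naive libraries together and 40 counts in the ligature libraries, a ratio of 47.3 after scaling (exact 95% interval 8.02 to 1910, counting error only). Its call (edgeR adjusted p = 0.0441) was lost when any naive or any ligature library was left out, at adjusted p = 0.0583 to 0.109.

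The fixed lists with members in the table moved as follows. All 3 measured antimicrobial genes, Defb3, Defb14 and the peptidoglycan-binding Pglyrp4, fell, also when adjusted over the list alone; 2 of 3 stayed lower with TMM. In the wound and stress list Areg and Hbegf fell with the deposited factors and with TMM, and also when adjusted over the list alone. Of the glycolysis and hypoxia genes only Adm, which encodes the vasodilator adrenomedullin, fell (log2 fold change -1.01), and Pfkp and Vegfa did not pass the test (Pfkp rose with a batch term, 0.36); this list had a median of -0.07, which TMM turned to 0.29, while camera gave its direction as up. Camera called none of these 3 lists in this comparison (adjusted p = 0.308, 0.308 and 0.957; 0 of 3 at an unadjusted p under 0.05), with a preset or an estimated correlation, and fry, which does not compare a list with other genes, called 3.

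Single members stood for the remaining lists. Prostaglandin synthase Ptgs2, the cytokine signalling inhibitor Socs3 and the Toll-like receptor adaptor Myd88 fell, with log2 fold changes of -1.70, -1.21 and -0.41. The Myd88 call was lost with TMM (-0.05) and without ligature replicate 2 (-0.32). Krt10, a keratin of differentiating suprabasal cells, rose by 0.64 ± 0.22 (edgeR adjusted p = 0.0182), and the call was lost without naive replicate 4 (0.58) or without ligature replicate 1 (0.42). The glucosylceramide synthase Ugcg fell by 0.34 with the deposited factors, stood at 0.03 with TMM and was not called without ligature replicate 2 (-0.27). Of the 17 cell type lists 1 had a gene in the table, the macrophage marker Cd68. It fell from 286.8 ± 54.6 to 179.7 ± 10.2 (log2 fold change -0.67 ± 0.16, edgeR adjusted p = 0.00402), and the call was lost with TMM (-0.31). Markers of neutrophils, T cells, fibroblasts and the other cell types were not in the table.

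In the list of immediate early and rapid-response genes, written after the gene names had been seen, all 30 measured members fell with the ligature. Fos (ENSMUSG00000021250) fell from 13550 ± 1370 (n = 4) to 7102 ± 774 (n = 3), Egr1 from 17870 ± 1210 to 8899 ± 683, and Atf3 from 1731 ± 503 to 422.3 ± 114, with log2 fold changes of -0.93, -1.01 and -2.04. The list median was -0.74, and camera gave an adjusted p of 2.65e-07; the call was lost at adjusted p = 0.2 with an estimated correlation. With TMM 20 of the 30 members were called lower and the median was -0.37. All 5 measured members of the mitosis list, Mki67, Aspm, Kif14, Racgap1 and Neil3, rose, by 0.40 to 0.74 on the log2 scale (camera adjusted p = 0.00145, and adjusted p = 0.2 with an estimated correlation), and all 5 were called higher with TMM as well. This list of 11 genes was also written after the gene names had been seen. Of the 20 genes of the cell cycle list fixed beforehand only 1, Mki67, was in this selected table, so the others could not be tested.

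**Figure D1:**
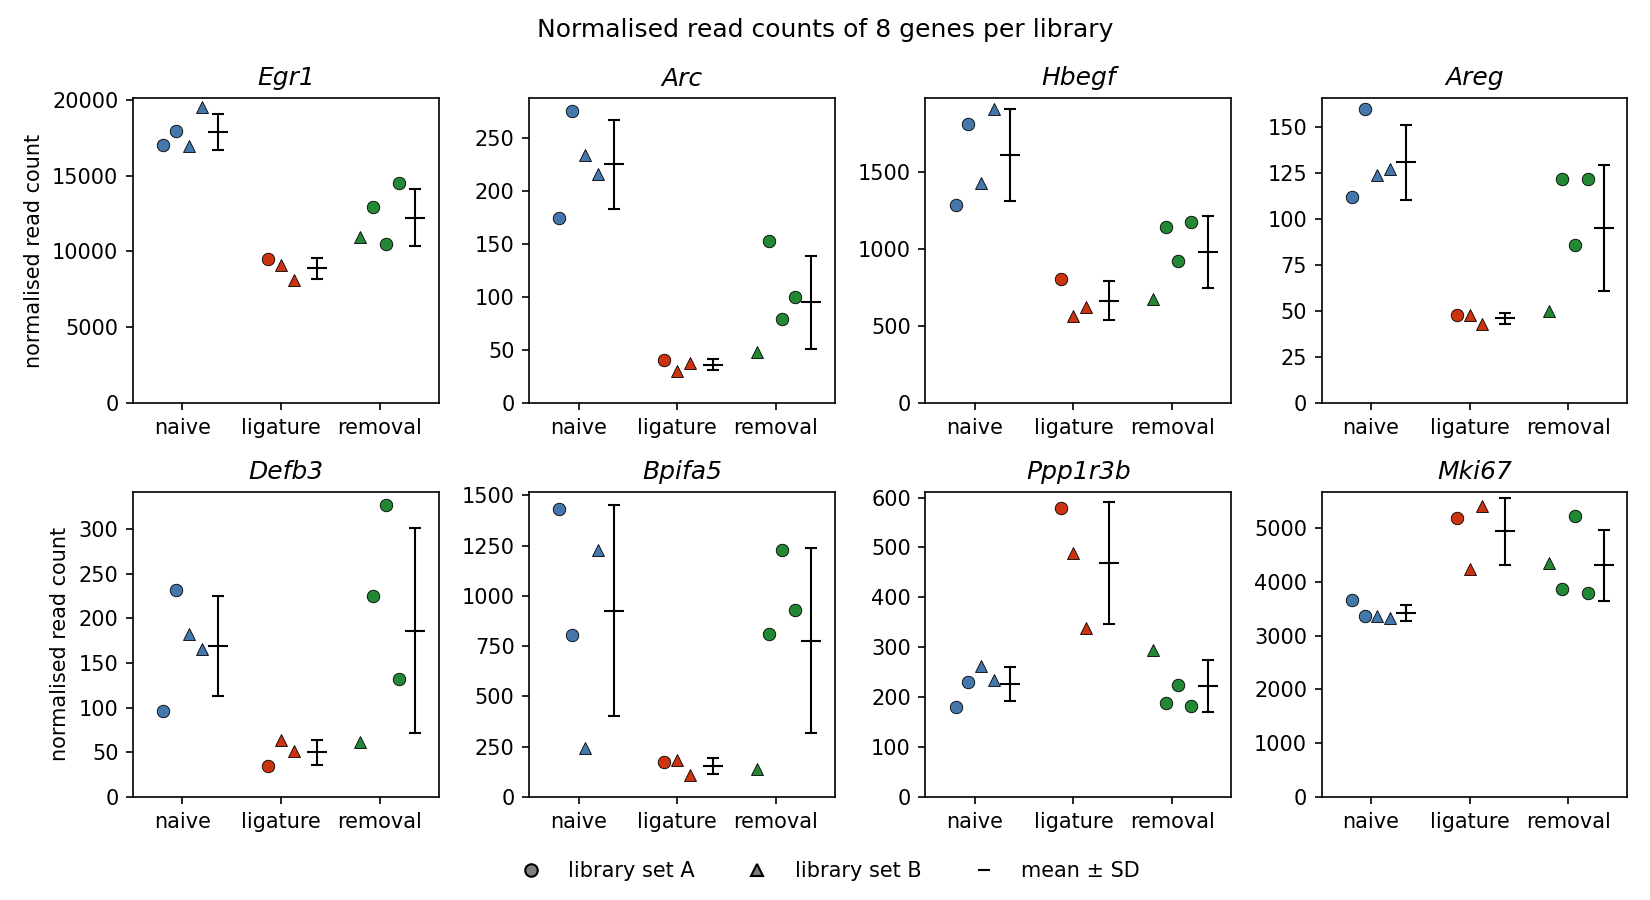
Normalised read counts (y axis, linear, from 0) of 8 genes in the naive (n = 4), ligature (n = 3) and removal (n = 4) libraries, 1 point per library, with circles for library set A, triangles for set B and bars for the mean ± SD. Areg lies at 46.06 ± 2.84 in ligature libraries against 130.8 ± 20.5 in naive ones, and Mki67 lies at 4938 ± 623 against 3426 ± 152.

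After removal of the ligature, Hbegf and 22 of the 30 measured rapid-response genes were lower than in naive epithelium (14 of 30 with TMM), and a smaller number of genes was called. Hbegf (ENSMUSG00000024486) fell from 1610 ± 300.2 normalised counts (SD, n = 4) to 980.1 ± 233.4 (n = 4), a log2 fold change of -0.72 ± 0.19 (SE; edgeR adjusted p = 0.0139). Zbtb16 (ENSMUSG00000066687), a zinc finger repressor, fell from 221.3 ± 189 to 46.3 ± 10.9, a log2 fold change of -2.24 ± 0.50 (edgeR adjusted p = 0.0119). Ptpn4, a tyrosine phosphatase, rose from 379.8 ± 24.8 to 579.7 ± 82.8, a log2 fold change of 0.61 ± 0.11 (edgeR adjusted p = 0.00778).

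Between removal and naive, 66 of 176 genes were called, 23 higher and 43 lower. With TMM factors 72 were called, 50 higher and 22 lower, so the share of higher calls was 34.8% with the deposited factors and 69.4% with TMM; the median log2 fold change was -0.17 and 0.03. All 66 calls kept their direction within both library sets and were among the 126 genes called with a batch term (40 higher, 86 lower). The selection of the table favours this agreement as well. The count was 48 without removal replicate 1, and 38, 42 and 43 without removal replicate 3, naive replicate 4 or naive replicate 1. In 77 of the 176 genes the libraries of the groups did not overlap, against 2.86% of genes by chance, though the genes of this table were selected for such differences.

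The other genes with large rises were Vma21, an assembly factor of the proton-pumping vacuolar ATPase, the DNA glycosylase Neil3, Lnpk, which shapes the endoplasmic reticulum, and Msi1, at log2 fold changes of 0.58, 0.58, 0.53 and 0.52. The Lnpk call was lost without naive replicates 1, 2 or 3 or removal replicates 3 or 4 (0.44 to 0.54), and the Msi1 call in 9 of the 11 fits with a library left out (0.37 to 0.60). Fam71a and Iqcn fell by 3.28 and 1.74 on the log2 scale, and Atf3 fell to 673 ± 204.7 counts. Ptgs2 fell by 1.34 ± 0.34 and Socs3 by 0.85 ± 0.21; the Socs3 call was lost with TMM (-0.66, adjusted p = 0.0503 in edgeR). Adm and the vascular growth factor Vegfa fell by 0.61 and 0.32. Both calls were lost with TMM; the Vegfa call was also lost when any naive or removal library was left out (-0.35 to -0.28), and the Adm call without naive replicates 1, 3 or 4 or removal replicates 1, 3 or 4 (-0.63 to -0.50). Scgb2b12 reads came from removal replicate 1 alone, with 49 counts there and 0 in the other removal libraries, and the gene was not called.

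Among the fixed lists, 1 of 3 antimicrobial genes fell (Defb14, log2 fold change -0.53 ± 0.17). Its call was lost with TMM (-0.33) and without naive replicates 1, 3 or 4 or removal replicates 1 or 3 (-0.54 to -0.42). Defb3 and Pglyrp4 stood at 0.14 and 0.01. In the wound and stress list Hbegf fell, and Areg stood at -0.46 ± 0.26 (edgeR adjusted p = 0.151). Of the glycolysis and hypoxia genes 2 of 3 fell. The same calls were made for these genes when adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.709, 0.328 and 0.601; 0 of 3 at an unadjusted p under 0.05), and fry called 2. The antimicrobial median was 0.01, its mean -0.13 and the camera direction down. Krt10, Myd88 and Cd68 did not pass the test over all genes (log2 fold changes 0.50, -0.25 and -0.37), and Krt10 and Cd68, each the only measured member of its list, had unadjusted p = 0.0314 and 0.0263 in edgeR. With a batch term Krt10, Myd88, Cd68 and Areg were all called in this comparison (edgeR adjusted p = 0.048, 0.0167, 0.0428 and 0.0426). Ugcg stood at -0.01, and Mki67 rose by 0.33 ± 0.12 (edgeR adjusted p = 0.0423), a call lost when any naive library, removal replicate 1 or removal replicate 3 was left out (0.22 to 0.36).

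Of the 30 immediate early and rapid-response genes, 22 fell after removal relative to naive (median log2 fold change -0.50, camera adjusted p = 3.91e-08, and adjusted p = 0.256 with an estimated correlation). Adjusted over the list alone the count was 25, with TMM it was 14 and without removal replicate 1 it was 18. Egr1 fell by 0.55 ± 0.12 and Fos by 0.44 ± 0.12. Of the 5 genes of the mitosis and chromosome maintenance list, 2 rose, Mki67 and the DNA glycosylase Neil3. The list had camera adjusted p = 0.00709, and adjusted p = 0.291 with an estimated correlation. When adjusted over the list alone, 3 of its genes rose. With TMM 4 were called higher, and 1 was when any naive library, removal replicate 1 or removal replicate 3 was left out.

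Relative to the ligature group, removal libraries had more transcript of the antimicrobial genes Defb3 and Pglyrp4 and less of the glycogen-targeting subunit Ppp1r3b. Defb3 (ENSMUSG00000039775), a beta-defensin, rose from 49.78 ± 14.2 (n = 3) to 186.2 ± 115 (n = 4), a log2 fold change of 1.90 ± 0.50 (edgeR adjusted p = 0.0276). Pglyrp4 rose by 0.79 ± 0.22 and Areg by 1.04 ± 0.29 (both edgeR adjusted p = 0.0276). Ppp1r3b (ENSMUSG00000046794) fell from 468.5 ± 122 to 222 ± 51.4, a log2 fold change of -1.08 ± 0.21 (edgeR adjusted p = 0.0221).

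In this comparison 35 of 176 genes were called, 30 higher and 5 lower. TMM gave 29 calls, 17 higher and 12 lower, so the share of higher calls was 85.7% with the deposited factors and 58.6% with TMM, and the median log2 fold change was 0.20 and 0.04. Median-of-ratios factors over the table gave 46 calls, 16 higher and 30 lower. Which direction prevailed therefore depended on the scaling. With a batch term 47 genes were called, including 34 of the 35, and 34 of the 35 had the same direction within both library sets. The edgeR count was 0 without ligature replicate 1, ligature replicate 2, removal replicate 2 or removal replicate 4, 3 without ligature replicate 3, 21 without removal replicate 3 and 49 without removal replicate 1. In each of the 4 fits with 0 calls, 49 to 72 genes had an unadjusted p under 0.05, DESeq2 with the deposited factors called 36 to 50, and all 35 genes kept their direction. In 52 of the 176 genes the libraries of the groups did not overlap, against 5.71% by chance for unselected genes. The genes of this table appear to be selected on these groups, so that rate is no fair measure here.

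The largest rises were in Uox, the enzyme that breaks down uric acid, Bpifa5, the C-type lectin Clec2e, Defb3 and Ankk1, at log2 fold changes of 2.88, 2.32, 1.92, 1.90 and 1.48. The Bpifa5 call was lost with a batch term. Removal replicate 1 was the lowest removal library for each of these 5 genes. Its Bpifa5 count was 137.3 against 810.4 to 1227 in the other removal libraries, within the 108.8 to 182.0 of the ligature libraries. Its Clec2e count was 30.15 against 79.09 to 82.38 in the other removal libraries, above the 12.65 to 21.30 of the ligature libraries. Ppp1r3b, the transcriptional corepressor Nab2 and Pdlim4 fell, by 1.08, 0.52 and 0.33. The gene model 2310057J18Rik, which also fell, lay outside the naming rule and was chosen after its values were seen; it stood at 71.09 ± 76.71 in ligature libraries and 4.828 ± 6.471 after removal. Of the antimicrobial genes 2 of 3 rose, and 0 were called in edgeR when any ligature library or removal replicate 2, 3 or 4 was left out. In the wound and stress list Areg rose, and Hbegf (0.56) rose only when adjusted over the list alone; no glycolysis and hypoxia gene was called. Camera called none of these lists (adjusted p = 0.303, 0.304 and 0.304; 0 of 3 at an unadjusted p under 0.05), and fry called 2. Ptgs2, Krt10, Socs3, Myd88, Mki67, Pfkp and Cd68 did not pass the test. With a batch term Socs3 rose (edgeR adjusted p = 0.028), and Pfkp and Vegfa fell (0.0367 and 0.038), which made 2 of 3 glycolysis and hypoxia genes lower.

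Of the immediate early and rapid-response genes 12 of 30 rose after removal relative to the ligature group, among them Fos (0.49 ± 0.13), Egr1 (0.46 ± 0.13) and Arc (1.38 ± 0.34). The list had camera adjusted p = 0.000376, and adjusted p = 0.316 with an estimated correlation. Adjusted over the list alone 15 rose, and 3 were called with TMM. No gene of the mitosis and chromosome maintenance list was called. That list had a median of -0.20 (camera adjusted p = 0.00655, and adjusted p = 0.316 with an estimated correlation).

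Set side by side, most genes that changed with the ligature lay nearer to naive after removal. Of the 100 genes lower with the ligature, 96 were closer to naive in the removal group, with a median log2 fold change of -0.79 in ligature and -0.38 in removal. Of the 50 higher genes 44 were closer, with medians of 0.48 and 0.29. Selecting genes on the ligature fold change favours such a shift. All 35 genes called between removal and ligature were ligature calls in the opposite direction, among them Areg, Defb3, Arc and Ppp1r3b. They were 30 of the 100 lower and 5 of the 50 higher ones (17 and 1.42 for independent lists). The comparisons are not independent, since both use the same ligature libraries with opposite sign, which favours opposite calls. In the same direction, 41 genes were lower and 16 higher in both treated groups than in naive, such as Hbegf, Atf3, Ptpn4 and Msi1. Independent lists would give 24.4 and 6.53, but both comparisons share the naive libraries, which favours calls in the same direction.

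As shares of the 150 ligature calls, 38% (exact binomial 95% interval 30.2 to 46.3) were also called after removal in the same direction and 23.3% (16.8 to 30.9) in the opposite direction between removal and ligature. These intervals treat genes as independent and do not measure the spread between libraries. With a library left out the shares were 20.8% to 45.5% and 0% to 32.2%. The same-direction share was 68.2% with a batch term, 57.9% with TMM, 53.5% with median-of-ratios factors and 30.2% with the replicate block. The opposite share was 26.1%, 21.9%, 36% and 5.76% in the same order. The size of both shares therefore depended on the processing. Across the 176 genes, which are not independent replicates, the fold changes of the treated groups against naive had a correlation of 0.798 (Spearman 0.782), a covariance of 0.567 and the same sign in 92% of genes. Simulated unchanged groups gave a correlation of 0.474 and a covariance of 0.0417, a covariance difference of 0.525. The simulation held no set effects and no selection of genes, so this difference is not an excess over chance for a table selected on these groups. The covariance was 0.405 and the difference 0.363 without Scgb2b12, and the covariance was 0.329 without removal replicate 1. With the naive libraries split between the comparisons, the covariance was 0.435 to 0.599 (0.253 to 0.412 without Scgb2b12), the same-sign share 83.5% to 94.3%, and 0 to 22 genes were called in both.

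**Figure D2:**
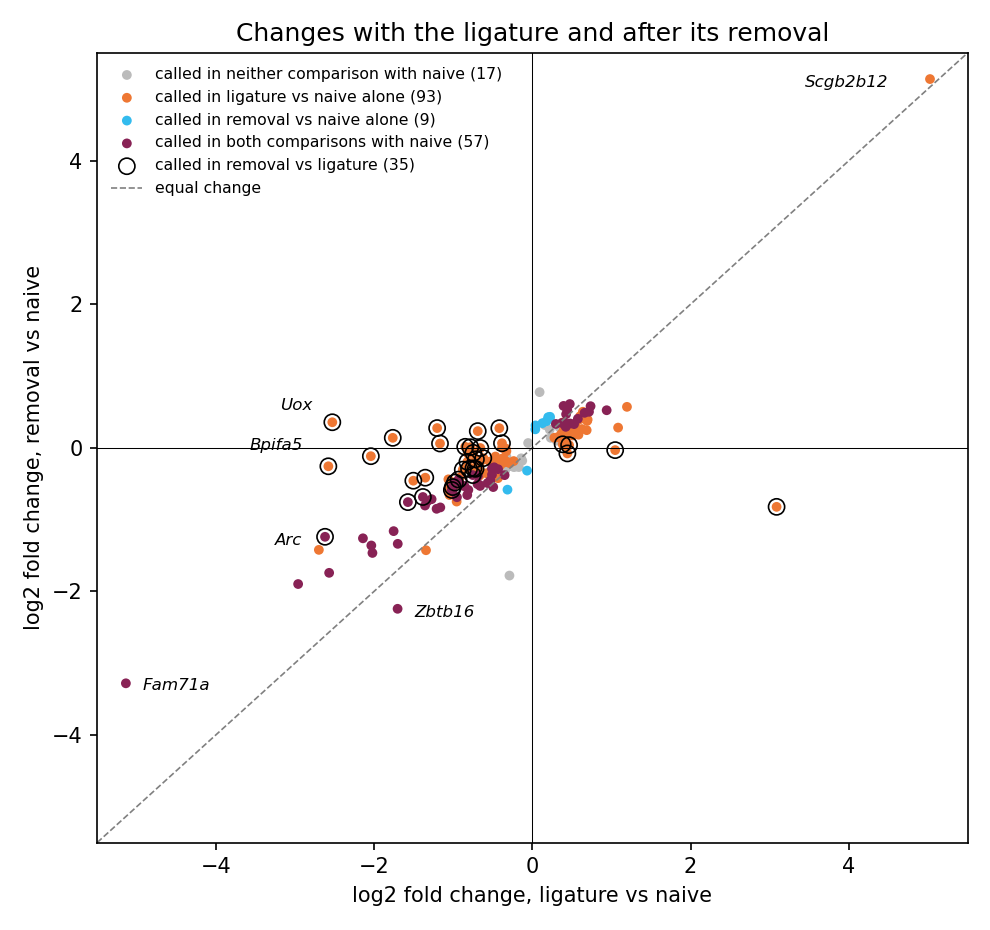
Log2 fold change of each of 176 genes with the ligature (x axis) and after its removal (y axis), both against naive, coloured by the comparisons in which edgeR called the gene, with a ring around the 35 genes called between removal and ligature and a dashed line of equal change. In both comparisons with naive 57 genes were called, 93 with the ligature alone and 9 after removal alone.

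The removal libraries were not alike. On an axis from the naive mean (0) to the ligature mean (1), removal replicate 1 stood at 0.746 over the 119 genes called with the ligature outside the immediate early list, Scgb2b12 left out, and the other removal libraries stood at 0.309 to 0.422. Over the 30 immediate early and rapid-response genes it stood at 0.689, within the 0.416 to 0.767 of the other removal libraries. Without it, 49 genes were called between removal and ligature and 48 between removal and naive.

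**Figure D3:**
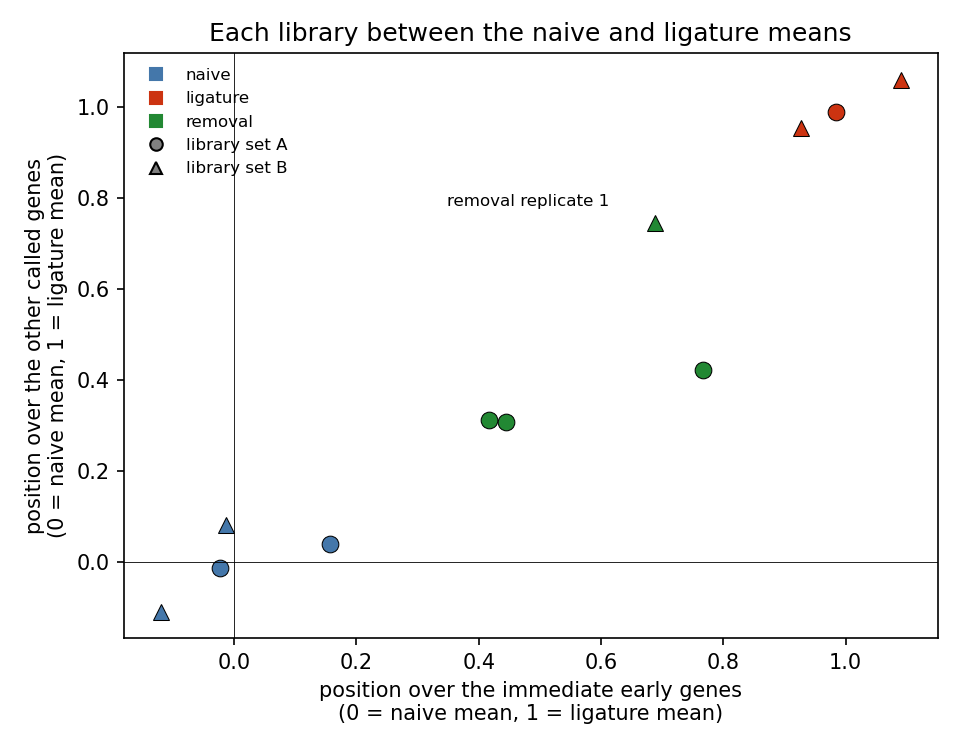
Position of each library between the naive mean (0) and the ligature mean (1), over the 30 immediate early and rapid-response genes (x axis) and 119 other genes called between ligature and naive (y axis, without Scgb2b12), with circles for library set A and triangles for set B. Removal replicate 1 stands at 0.689 and 0.746, and the other removal libraries at 0.416 to 0.767 and 0.309 to 0.422.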

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

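The tests of the batches and of a wrong label were chosen only after the result was seen, and so was the list of immediate early and rapid-response genes itself. Over 94 groups of 4 libraries checked (naive and removal libraries, for named genes, list scores, size factors and table totals), 5 libraries stood far from the other 3 of their group, where chance marks about 1 in 20 groups, or 4.7 here. Clec2e had a normalised count of 30.15 in removal replicate 1 and 79.09 to 82.38 in the other removal libraries. Scgb2b12 stood at 54.71 in removal replicate 1 and at 0 in the others, and at 0.879 (1 count) in naive replicate 4. Mki67 stood at 3653 in naive replicate 1 against 3328 to 3365 in the other naive libraries, and Vegfa at 1462 in the same library against 1320 to 1343.

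Removal replicate 1 lay near the ligature libraries. On an axis from the naive mean (0) to the ligature mean (1), over the 119 ligature-called genes outside the immediate early list (without Scgb2b12), it stood at 0.746, removal replicates 2 to 4 at 0.309 to 0.422 and the ligature libraries at 0.954 to 1.06. Over the immediate early genes removal replicate 1 stood at 0.689, below the lowest ligature library (0.928, SD 0.0808). With each ligature library in turn held out of the axis it stood at 0.653 to 0.718, and the held-out libraries at 0.871 to 1.12. This argues only weakly against a ligature library with a wrong label. The genes of the table appear to be selected with the ligature libraries included, which favours positions near 1 for them even when held out. A set effect shared by the groups is argued against as the whole cause. With the set effect estimated from naive and ligature libraries subtracted, removal replicate 1 still stood at 0.752. The other removal libraries stood at no more than 0.416 (SD 0.0635). A set effect particular to the removal group cannot be told apart from this replicate, since it was the only removal library in set B. On the question of a wrong label, single genes went the other way. Smr2 (7 counts) and Scgb2b12 (49 counts) were found in removal replicate 1 and in the ligature libraries but in no other removal library. Its Bpifa5 count of 137.3 lay within the ligature range. Usp9y, a gene of the Y chromosome, had 30 counts in it and 0 in every other library, which sets it apart from the ligature libraries as well. A mixed sample or a smaller change after removal may still account for its position, and neither was tested.

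The 30 immediate early and rapid-response genes were lower in the ligature libraries, although such genes rise after acute stimulation. The deposited size factors as the whole cause are argued against by TMM scaling, which moved the median of all genes to near 0 and left 20 of 30 members called lower. The medians within library sets were -0.71 in set A, which holds 1 ligature library, and -0.85 in set B. They are no separate test of the batches. Every gene of the table differed between groups with the sets allowed for, so agreement within sets was largely fixed in advance. Tissue handling before RNA extraction could move these genes too, since the Dispase step itself may induce them. The 3 measured heat shock chaperones were also called lower with the ligature (median log2 fold change -0.82), a pattern that handling could give as well. Handling cannot be told apart from the groups, because within groups the immediate early and heat shock scores had r = 0.445 (permutation p = 0.25; Spearman 0.5, permutation p = 0.24; r = 0.553 without the 2 farthest libraries and 0.513 within group and library set; 11 libraries, 1 relation tested), and the collection order of the samples is unknown. A difference between the groups themselves stays open and was not tested.

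The counts of called genes were set against all other splits of the same libraries. For ligature against naive 1 of 35 splits, the real one, gave as many calls as 150, and the highest other gave 68, a split that moved naive replicate 3 to the ligature libraries. For removal against naive 1 of 35 splits gave as many as 66, and the highest other gave 1. The genes of the table had been selected on these same groups, so neither count excludes chance. For removal against ligature 2 of 35 splits gave as many as 35, so chance was not excluded; the other one placed removal replicate 1 with the ligature libraries and gave 42 calls, which points to a structure of the samples. Its arms follow the library sets except for ligature replicate 1. The split exactly along the sets gave 10 calls, and the real comparison with a batch term gave 47.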

How the results depend on the processing

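The deposited size factors, used in place of the TMM scaling of the written design, the batch term, DESeq2 with the deposited factors and the fits without Scgb2b12 were chosen only after the data were seen. The count for ligature against naive stayed within 1.5 times of 150 under all alternatives run (130 to 154 with a library left out). For removal against naive (66) it was 126 with a batch term, 130 with that term in DESeq2, 128 with limma on the batch-corrected values, and 38 (without removal replicate 3) to 78 with a library left out. For removal against ligature (35) it was 53 in DESeq2 with its own factors (21 higher, 32 lower), 61 in DESeq2 with the batch term, and 0 to 49 with a library left out; in the fits with 0 calls the smallest adjusted p was 0.0518 to 0.0602, and all 35 genes kept their direction. Of the 3 fixed lists tested, fry called 3, 2 and 2, against 0 with camera. The covariance (0.567) was 0.329 (without removal replicate 1) to 0.626 with a library left out and 0.691 with no filter on low counts. The share called again in the same direction (38%) was 53.5% with median-of-ratios factors, 57.9% with TMM, 58% in DESeq2 with its own factors, 68.2% with a batch term and 20.8% (without removal replicate 3) to 45.5% with a library left out. The opposite share (23.3%) was 36% with median-of-ratios factors, 40.3% in DESeq2 with its own factors and 0% to 32.2% with a library left out. Ugcg with the ligature turned from -0.34 to 0.0248 with median-of-ratios factors, 0.0247 in DESeq2 with its own factors and 0.0262 with TMM. For the changes in this paragraph the cause was not tested.

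Of the named genes called, 17 of 23, 9 of 17 and 0 of 11 stayed called under every alternative in the order of the comparisons above, the last because of the fits with 0 calls. Replicate numbers did not pair the libraries: 3 of 10 same-numbered pairs had deviations correlated above 0.1 (range -0.511 to 0.525). Adding the replicate block gave 8 calls for removal against ligature, and shares of 30.2% (same direction) and 5.76% (opposite); the cause was not tested. The depth of the libraries is unknown, so how far it limits genes with few counts cannot be stated.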

Other observations

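All lists, genes and tests here were chosen only after the gene names or values had been seen. Genes of NF-kappaB and Toll-like receptor signalling were lower with the ligature. All 8 measured members fell (Nfkbia, Nfkbiz, Map3k8, Myd88, Tnfaip2, Cebpb, Ptgs2 and Litaf), with a median log2 fold change of -0.66, camera adjusted p = 0.031, and adjusted p = 0.286 with an estimated correlation. With TMM 4 of 8 were called lower and the median was -0.30. Nfkbia, the inhibitor that holds NF-kappaB in the cytoplasm, fell from 4133 ± 618 normalised counts (n = 4) to 2043 ± 112 (n = 3), and Nfkbiz, a nuclear regulator of its targets, from 2548 ± 230 to 1385 ± 256. After removal 2 of the 8 were lower than in naive, 6 with a batch term, 7 with limma on the batch-corrected values and 7 in DESeq2 with the batch term (camera adjusted p = 0.0329, adjusted p = 0.291 with an estimated correlation and 0.0577 with TMM), and 2 were higher than in the ligature group, Nfkbia and Nfkbiz (camera adjusted p = 0.0919). The immediate early list holds 4 of the 8 genes, so the lists are not independent. Fixed lists hold Ptgs2, Socs3, Myd88 and Mki67 of the added lists.

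The heat shock chaperones Hspa1a, Hspa1b and Dnajb1 fell with the ligature, by 1.35, 0.82 and 0.80 on the log2 scale, and rose from ligature to removal by 0.94, 0.62 and 0.51, in both cases also with TMM. The list had camera adjusted p = 0.104 with the ligature and 0.0499 between removal and ligature, and for the latter adjusted p = 0.0644 with a batch term and adjusted p = 0.316 with an estimated correlation. Relative to naive none of the 3 passed edgeR's test after removal (log2 fold changes -0.42, -0.20 and -0.29), and 3 were called lower with a batch term. Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain.

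Between the library sets 53 genes were called, 16 higher and 37 lower in set B. The largest difference was in Matn4, a matrilin of the extracellular matrix, at a log2 difference of 4.08. Its normalised counts lay between 6.54 and 29.54 in the 6 libraries of set A and between 188.7 and 405.1 in the 5 of set B, whatever the group. Angptl4, a regulator of lipoprotein lipase, was higher in set B by 1.57, and Krt10 was lower by 0.48.

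Usp9y, a gene of the Y chromosome, had 30 counts in removal replicate 1 and 0 in each of the other 10 libraries, although the labels describe all mice as male. This single gene with few counts does not settle the sex of the libraries. Smr2, which encodes a submaxillary gland protein, had 5, 3 and 2 counts in the ligature libraries, 7 in removal replicate 1 and 0 in each of the others. Scgb2b12 was detected in the same 4 libraries and, with 1 count, in naive replicate 4. Dlx4os and Oip5os1 overlap other genes on the opposite strand, and their counts cannot be separated from those of the partner genes without knowing the strand setting.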
